A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

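The series holds 12 hybridizations to 2-colour arrays, each of total RNA from 1 fermentation by 1 strain of Saccharomyces cerevisiae. Strains ITD00185 and T73 were each sampled at 48 h and at 96 h in synthetic agave must at 28 ºC, with 3 arrays per strain and time. Per the labels the 3 arrays of a group are biological replicates. RNA was amplified linearly and labelled by the indirect cDNA method, per the labels' protocols. The strain's RNA carried Cy5 on all 12 arrays, and the other channel carried a Cy3 sample mix, whose strain is given as mixed and whose time point is that of the array. No array had the dyes exchanged, so a bias of a dye toward a gene cannot be separated from the ratio of that gene within a group. It falls out of a difference between strains if it is of equal size on every array. The labels do not give the makeup of the mix.

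The deposited values are log2 ratios of the 2 channels, 1 value per probe and array, in a table the authors gave to the Gene Expression Omnibus. How the arrays were scanned, corrected for background, filtered and normalized is not given in the sources used here. The array medians ran from -0.03 to 0.42 and the standard deviations over probes from 1.03 to 2.08, so that the arrays had not been brought to one median or one spread, and whether any centring was applied is unknown. The direction of the ratio is not stated either. It is likely strain over mix, from the order of the channels and dyes in the labels and from the usual convention of test over reference, and every signed value rests on that reading. The table held 6246 probes, of which 3 had no value on any array, and between 5657 and 6116 had a value on each array. Of all values, 32 were beyond 10 in size on the log2 scale, far outside the rest. They were kept, and genes that rest on them are named as such. Signal and background intensities were not used here, so the precision behind each ratio is limited by the number of arrays and cannot be given per spot.

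Probe names were matched to the gene table of the reference strain S288C, 5753 by systematic name and 34 by synonym, while 459 reading frames were not in that table and kept their own names. Probes of the same gene were averaged, which left 6214 genes, 31 of them with 2 or more probes. Genes were tested when each of the 4 groups had values on at least 2 arrays, which 5474 genes met, 4656 of them with a gene symbol. A linear model with 4 group means was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with moderated tests, 8 residual degrees of freedom and a further 3.16 from the prior. P values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. Tests were two-sided.

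The comparisons were ITD00185 against T73 at 48 h, at 96 h and averaged over both times, the change of this difference from 48 h to 96 h, and the change between the times in each strain and in their mean. In a difference between strains at 1 time the mix falls out, provided that the same mix was used on the arrays of that time. A change between times within a strain compares ratios to mixes labelled with different times and is reported as a change of the ratio to the mix, not of expression. Hybridization to probes designed on another genome also depends on whether the strain carries the gene and on its sequence, which the arrays did not measure separately.

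Before the data were examined, 41 gene lists, the model, the thresholds, the alternatives and the rule for naming genes were written down. Of these lists 40 had at least 5 measured genes. The list of mitochondrially encoded genes had 0. Lists were tested against all other genes with limma's cameraPR and its preset correlation between genes of 0.01. The plan named camera on the expression values, which does not accept missing values, so the ranking statistic of the full fit was used in its place. A test by camera with the correlation estimated from the data was run on the 4807 genes with a value on every array. It called 0 of 40 lists in each of the 3 comparisons tested, and its adjusted p stands beside the list calls reported. Counts of members past the test are given over all 5474 genes and as adjusted over the list alone.

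The rule for naming genes took, at each time, the 8 largest differences in each direction among genes with a symbol, a value on all 6 arrays of that time, a call, and no overlap between the arrays of one strain and those of the other. It added, at each time, up to 4 members past the threshold, smallest adjusted p first, of each list that was called or had at least 2 such members. The 5 largest changes of the difference in each direction and 11 genes fixed by name completed it. From the genes this rule gave, those printed are mainly ones whose call held with each single array left out, a choice made after the values were seen. BUB1, LCP5, MIG1, ENV11, YJU2 and AGP2 were taken by the rule and lost a call without one array or another, and their values are given with that limit. A few further genes were chosen from the called lists after their values were seen.

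The fit was tested on simulated data with the group means, missing values and pooled gene variances of these arrays. The simulated noise was normal, independent between genes and of equal size on every array, which the real noise was not. The rates below therefore do not cover the larger spread at 48 h, an array that stands apart, or lists of genes that vary together. In the simulated 48 h comparison 71% of genes changed by 2 on the log2 scale and 13% of genes changed by 1 were recovered, and 4.55% of the calls were false. The simulated 96 h comparison recovered 72% and 7%, with 1.25% of the calls false. The simulated change between times recovered 34% and 1%, with 7.89% of the calls false. A list raised by 1 in the simulated data, the proteasome, was called in all 3 comparisons and 0 other lists were. Genes that did not pass are therefore not shown to be unchanged, least of all for the change between times.

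Alternatives covered the centring, scaling and quantile normalization of the arrays, the filter on missing values, the treatment of probes, the arrays entering a fit, weights for arrays, a block for the replicate number, the thresholds, and the leaving out of each array in turn. Removing the profile shared by the arrays, applying the scaled and quantile-normalized values to the lists, and the estimated correlation without ITD00185 48 h replicate 2 were added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.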

Results

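Total RNA of 2 strains of Saccharomyces cerevisiae was hybridized to 12 arrays with 2 colours during fermentation of a synthetic agave must at 28 ºC. T73 is a commercial wine yeast, and ITD00185 is taken as the agave strain of the series title. Each strain was sampled at 48 h and at 96 h, with 3 biological replicates per strain and time according to the labels. Each array gave log2 ratios of the strain to a mix of samples of the same time point for 5657 to 6116 probes. Signed values are ITD00185 minus T73 on the log2 scale, ± the standard error of the fit. The variance behind that error was moderated and shared by all 12 arrays, so it is not the spread of the arrays of 1 time. A positive value means higher in ITD00185 only if the deposited ratio is strain over mix, which is likely but not stated. All 12 arrays correlated positively across genes, with r from 0.20 to 0.90, also between strains, where r ran from 0.20 to 0.73. ITD00185 48 h replicate 2 stood apart from its group, with r of 0.40 and 0.50 across genes to replicates 1 and 3 against 0.81 to 0.84 to the ITD00185 arrays of 96 h. Its replicates 1 and 3 correlated at 0.73. The median standard deviation over the 3 arrays of a group was 0.50 for ITD00185 and 0.44 for T73 at 48 h, and 0.27 and 0.24 at 96 h.

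**Figure D1:**
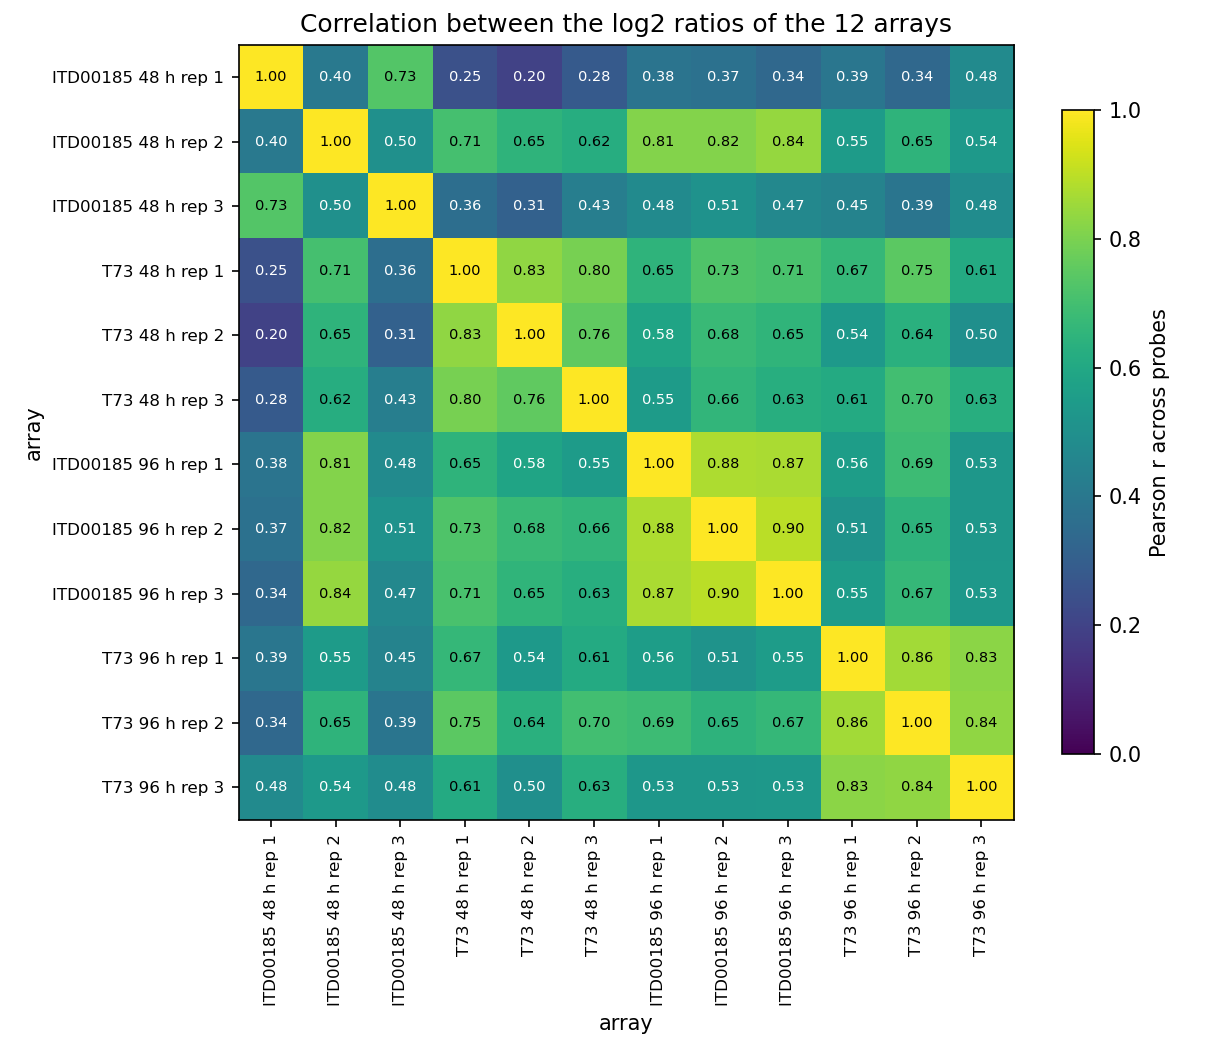
Pearson r across probes between the log2 ratios of the 12 arrays, ordered by time, strain and replicate, with the colour scale from 0 to 1. ITD00185 48 h replicate 2 correlated at 0.81 to 0.84 with the ITD00185 arrays of 96 h and at 0.40 and 0.50 with the other arrays of its own group.

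The first comparison asked which genes differed between the strains at 48 h. Among genes with a symbol and a value on all 6 arrays of this time, the largest differences in favour of ITD00185 were those of IRC9 (YJL142C) at 6.29 ± 0.28, AIF1, a mitochondrial apoptosis-inducing factor, at 5.67 ± 0.56, and BAT1, the mitochondrial branched-chain aminotransferase, at 5.11 ± 0.43. SPG1, needed for survival in stationary phase, was higher by 4.98 ± 0.33, ECM8 by 4.89 ± 0.35 and MST28 by 4.81 ± 0.95. FIT3, a cell wall protein that retains siderophore iron, differed by 4.58 ± 0.50, and MPH2, a permease for maltose and other alpha-glucosides, by 4.49 ± 0.53. ZNF1, a zinc cluster transcription factor, differed by 7.87 ± 0.51 but lacked a value on some arrays of this time. Among genes with a symbol, all 6 values and a call that held with each array left out, the largest differences in favour of T73 were those of the hypoxic gene repressor ROX1 (-7.33 ± 0.69) and of SDA1, which acts in ribosome biogenesis (-6.26 ± 0.82). The cell wall asparaginases ASP3-3 (-6.13 ± 0.23) and ASP3-1 (-5.91 ± 0.29) came next, near-identical copies that a probe may not separate. YAP1801, a clathrin assembly factor (-5.80 ± 0.74), RCF1, of the respiratory supercomplexes (-5.60 ± 0.96), and MIL1 (-5.55 ± 0.86) followed, with RCF1 at -3.66 with the shared profile removed. Differences larger than that of ROX1 rested on 2 values of T73 for TFA1 (-9.84 ± 1.02), ASP3-4 (-7.76 ± 0.61), ASP3-2 (-7.66 ± 0.65) and BRF1 (-7.47 ± 0.86), and for LCP5 (-9.01 ± 1.95), which moved to -4.61 without T73 48 h replicate 2 and to -13.41 without T73 48 h replicate 3. BUB1, a kinase of the spindle checkpoint, stood at -8.43 ± 2.29, but 1 of its values was beyond 10 in size and it moved to -4.70 without T73 48 h replicate 2. Its adjusted p was 0.0511 without ITD00185 48 h replicate 1. Of 5474 genes tested, 2164 differed at 48 h, 705 higher in ITD00185 and 1459 higher in T73, and 1877 of them by 2-fold or more. Among 4888 genes with all 6 values, the 3 arrays of each strain did not overlap for 1997 (40.9%, against 10% by chance). The median difference over all genes was -0.32, and with each array centred on its median it was -0.05, with 1001 genes higher and 1120 lower in ITD00185. The count was 1252 with the arrays scaled to one spread, 1265 after quantile normalization, 794 in a fit of only the 6 arrays of this time, 1414 without ITD00185 48 h replicate 1 and 2832 without ITD00185 48 h replicate 2.

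Genes of sugar use, branched-chain amino acid synthesis and the citric acid cycle were more often higher in ITD00185 at 48 h. Of 14 measured genes for the use of sucrose, fructan and maltose, 9 were higher and 0 lower (9 and 2 adjusted over the list alone), with a median of 1.73. List medians ran from 0.04 to 0.51 on the ITD00185 arrays against -1.59 to -1.33 on the T73 arrays. MAL33, a maltose activator (3.61 ± 0.29), the isomaltase IMA1 (2.40 ± 0.32), MPH2 (4.49 ± 0.53) and the hexokinase HXK1 (2.81 ± 0.48) were among them. The MAL, IMA and MPH genes belong to families with close copies. Of 20 genes of hexose transport, 12 were higher and 1 lower (14 and 2 adjusted over the list alone), with a median of 1.23. HXT13 (2.10 ± 0.33, from 2 arrays of ITD00185) and HXT15 (1.97 ± 0.35), again near-identical, were higher. In branched-chain amino acid synthesis 8 of 11 genes were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 2.28. The isopropylmalate genes LEU2 (3.21 ± 0.28), LEU4 (3.00 ± 0.40) and LEU9 (2.28 ± 0.35) were among the higher ones. The permease for branched-chain amino acids, BAP2, differed by 3.88 ± 0.27. In the citric acid cycle 7 of 22 genes were higher and 0 lower (7 and 0 adjusted over the list alone), with fumarase FUM1 at 2.19 ± 0.32, aconitase ACO1 at 1.95 ± 0.36 and SDH2 of succinate dehydrogenase at 1.88 ± 0.32 (1.00 with scaled arrays). Of 36 genes of cell wall mannoproteins and flocculins 17 were higher and 2 lower (17 and 2 adjusted over the list alone), with the mannoprotein CWP2 at 3.76 ± 0.52 and the glucanase EXG1 at 2.24 ± 0.44. Of 23 glycolytic genes 7 were higher and 2 lower (7 and 2 adjusted over the list alone). The list medians of single arrays overlapped between the strains for glycolysis (0.24 to 0.82 in ITD00185 against -0.64 to 0.27) and for the cell wall (-0.67 to 0.40 against -0.71 to -0.27). The adjusted p of these 6 lists was 1.38e-05 for sucrose, fructan and maltose, 0.000321 for hexose transport, 2.4e-06 for branched-chain amino acids, 0.00202 for the citric acid cycle, 0.000561 for the cell wall and 0.00253 for glycolysis. With an estimated correlation none passed, at adjusted p = 0.365, 0.365, 0.365, 0.446, 0.48 and 0.48. All 6 kept their direction and their call under centring, scaling, quantile normalization and removal of the shared profile.

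Genes repressed by good nitrogen sources, ergosterol genes and chaperone genes were more often lower in ITD00185 at 48 h. Of 35 measured genes under nitrogen catabolite repression 19 were lower and 4 higher (21 and 4 adjusted over the list alone), with a median of -1.23. The ASP3 copies, which a probe may not separate, count as 4 of the lower genes and as 4 members in the list test. Other lower genes included the allantoate permease DAL5 (-5.44 ± 0.32), the allantoinase DAL1 (-4.14 ± 0.32), the urea permease DUR3 (-2.74 ± 0.37) and the GABA permease UGA4 (-1.96 ± 0.25). In ergosterol synthesis 14 of 25 genes were lower and 2 higher (17 and 2 adjusted over the list alone), among them ERG20 (-3.68 ± 0.33), ERG6 (-3.29 ± 0.33), MVD1 (-2.49 ± 0.33) and ERG3 (-2.06 ± 0.37). Of 30 heat shock proteins and chaperones 20 were lower and 2 higher (21 and 2 adjusted over the list alone), with a median of -1.94 that shrank to -1.05 with scaled arrays, -1.08 after quantile normalization and -0.59 with the shared profile removed. In the same order the median of nitrogen catabolite repression became -0.67, -0.78 and -0.97, and that of ergosterol, at -1.21 as deposited, became -0.74, -0.75 and -0.92. SSA4, of the 70 kDa heat shock family (-4.93 ± 0.64), SSE1 (-4.48 ± 0.70) and the cochaperone STI1 (-3.69 ± 0.61) were lower, and kept their calls at -2.63, -2.57 and -2.01 with the shared profile removed. With scaled arrays ERG20 stood at -2.25 and ERG6 at -1.41. HSP42 (-3.18 ± 0.45) also passed, but not with the shared profile removed (-1.20). The adjusted p of the lists was 0.000321 for nitrogen catabolite repression, 0.00809 for ergosterol and 0.00215 for chaperones, and adjusted p = 0.365, 0.446 and 0.446 with an estimated correlation. Without ITD00185 48 h replicate 2 the ergosterol list missed the threshold (median -0.94, adjusted p 0.068).

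Ribosomal and proteasome genes were more often lower in ITD00185 at 48 h in the values as deposited, but their lists were not called once the spread of the arrays was set equal. Of 128 cytosolic ribosomal protein genes 54 were lower and 3 higher (54 and 3 adjusted over the list alone), with a median of -0.70 that turned to 0.16 with scaled arrays, 0.24 after quantile normalization and 0.41 with the shared profile removed. RPL10, for example, went from -1.25 ± 0.26 to 0.04 with scaled arrays and 0.15 after quantile normalization. Genes named as A and B copies, which a probe may not separate, count as separate members of this list. Of 33 proteasome genes 17 were lower and 0 higher (22 and 1 adjusted over the list alone), with a median of -1.09 that became -0.04, -0.03 and 0.15 in the same order. Its lid subunit RPN6 moved from -1.09 ± 0.27 to 0.05 with the shared profile removed. Of 53 mitochondrial ribosomal protein genes 20 were lower and 1 higher (20 and 1 adjusted over the list alone), among them RSM10 (-2.54 ± 0.23) and MRP51 (-2.97 ± 0.51), which kept their calls with scaled arrays (-1.70 and -1.32). Of 61 genes of ribosome biogenesis 30 were lower and 4 higher (30 and 5 adjusted over the list alone). The medians of the last pair, at -1.08 and -1.06 as deposited, stayed negative with scaled arrays (-0.32 and -0.43), after quantile normalization (-0.36 and -0.48) and with the shared profile removed (-0.25 and -0.21). The adjusted p of these 4 lists was 0.00202, 0.00194, 0.0112 and 0.0297 as deposited, and adjusted p = 0.573, 0.526, 0.446 and 0.532 with an estimated correlation. After quantile normalization it was 0.193, 0.848, 0.154 and 0.193. The list of ribosome biogenesis was also lost without ITD00185 48 h replicate 1 (adjusted p 0.0595), T73 48 h replicate 1 or T73 48 h replicate 2. For sulfur assimilation and methionine synthesis, with 10 of 34 genes higher and 5 lower (10 and 5 adjusted over the list alone), the median was -0.02, the mean 0.23 and the call upward (adjusted p 0.0225, and adjusted p = 0.55 with an estimated correlation). It was lost without ITD00185 48 h replicate 1 (0.0595). In all, 22 of 40 lists were called at 48 h and 14 with the arrays scaled to one spread.

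**Figure D2:**
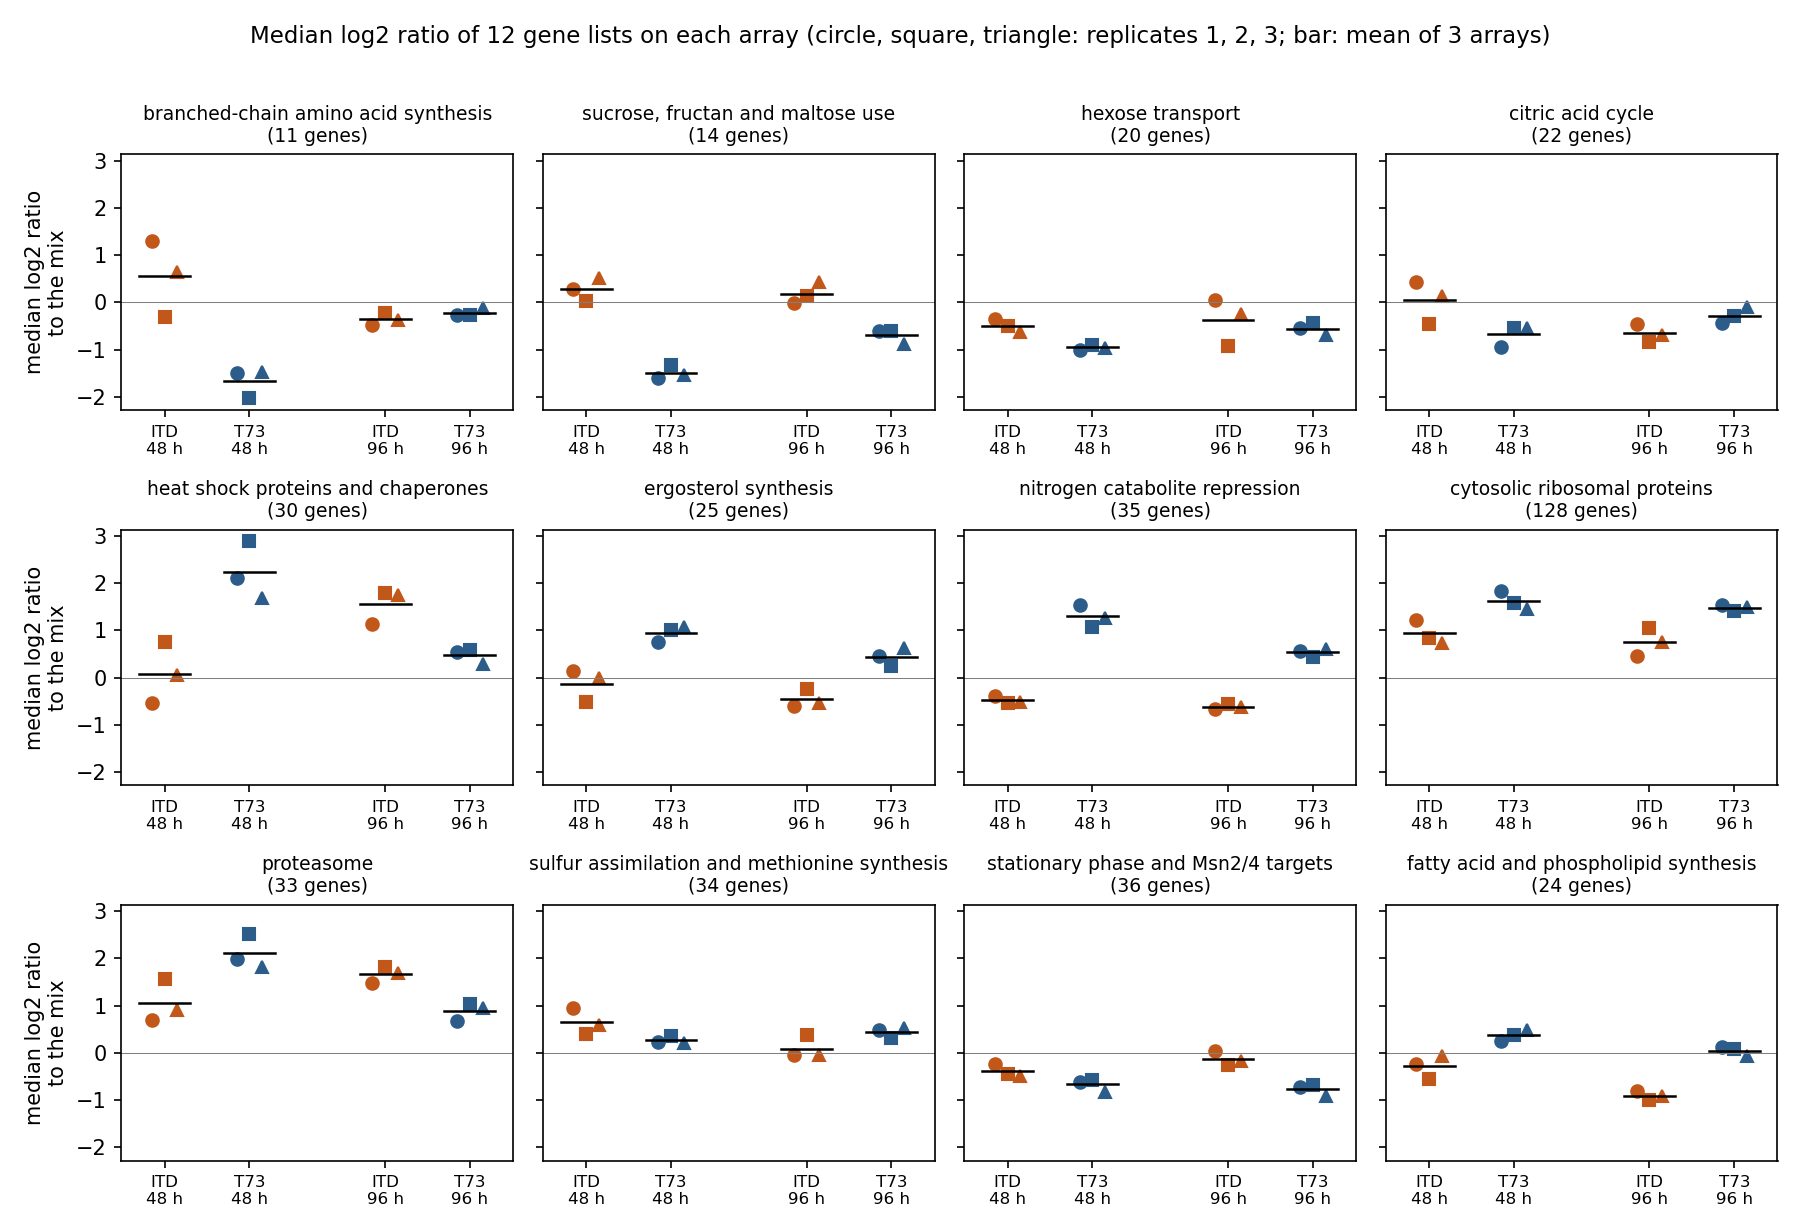
Median log2 ratio to the mix of the measured genes of 12 lists on each array, with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the mean of the 3 arrays. Nitrogen catabolite repression lay lower on the ITD00185 arrays at both times (-0.53 to -0.39 against 1.08 to 1.54 at 48 h). Heat shock proteins lay lower in ITD00185 at 48 h and higher at 96 h. At 48 h the order turned for cytosolic ribosomal proteins with the arrays scaled to one spread, and the proteasome median fell to -0.04.

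The second comparison asked which genes differed at 96 h. Among genes with a symbol, a value on all 6 arrays of this time and a call that held with each array left out, the largest difference in favour of ITD00185 was again that of IRC9 (6.93 ± 0.28), followed by ZNF1 (5.35 ± 0.45), MST28 (4.57 ± 0.95), the stress-induced hydrophilin GRE1 (4.55 ± 0.52), the epsin ENT3 (4.51 ± 0.66) and PIL1, a core protein of eisosomes (4.41 ± 0.68). Within the same limits the largest in favour of T73 were those of ASP3-2 (-8.75 ± 0.59), ASP3-4 (-8.39 ± 0.55), ASP3-3 (-7.09 ± 0.23) and ASP3-1 (-7.05 ± 0.29). They were followed by SSF1, which acts in ribosomal RNA processing (-5.55 ± 0.39), and DAL5 (-5.04 ± 0.32). The glucose repressor MIG1 (4.55 ± 1.09), ENV11 (4.39 ± 1.01), the splicing factor YJU2 (-5.60 ± 1.58) and AGP2 (-4.62 ± 1.22) were also among the largest, but each lost its call without at least 1 array. MIG1 had an adjusted p of 0.0613 and YJU2 of 0.106 without ITD00185 96 h replicate 2, ENV11 of 0.0576 without T73 96 h replicate 3, and AGP2 of 0.078 without T73 96 h replicate 1. Of 5474 genes 1229 differed at 96 h, 656 higher in ITD00185 and 573 higher in T73, and 1088 of them by 2-fold or more. The 3 arrays of each strain did not overlap for 3084 of 5296 genes with all 6 values (58.2%, against 10% by chance). The median over all genes was -0.01. The count was 537 without T73 96 h replicate 1, 2466 in a fit of only the 6 arrays of this time and 3178 with weights for arrays. In fits of each time alone more genes passed at 96 h than at 48 h, the reverse of the order in the main fit.

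Genes under nitrogen catabolite repression and for ergosterol were again more often lower than higher in ITD00185 at 96 h, and so were those of cytosolic ribosomal proteins and phospholipid synthesis. In nitrogen catabolite repression 17 of 35 genes were lower and 4 higher (19 and 4 adjusted over the list alone), with a median of -1.17, DAL1 at -2.85 ± 0.32, DUR3 at -2.47 ± 0.37 and UGA4 at -2.37 ± 0.25. The ASP3 copies again count as 4 of the lower genes. Of 128 cytosolic ribosomal protein genes 46 were lower and 2 higher (58 and 3 adjusted over the list alone), with a median of -0.62 that grew to -1.17 with scaled arrays, -1.25 after quantile normalization and -1.09 with the shared profile removed. RPL23B stood at -2.38 ± 0.29 and RPL10 at -1.76 ± 0.26. A and B copies such as RPL23B, which a probe may not separate, again count as separate members in the counts and in the list test. In fatty acid and phospholipid synthesis 10 of 24 genes were lower and 2 higher (12 and 2 adjusted over the list alone), among them the inositol phosphate synthase INO1 (-2.84 ± 0.43), the phosphatidylserine synthase CHO1 (-1.88 ± 0.29) and EPT1 (-2.71 ± 0.35). In ergosterol synthesis 10 of 25 were lower and 0 higher (14 and 0 adjusted over the list alone), with MVD1 at -1.95 ± 0.33. In sulfur assimilation and methionine synthesis 10 of 34 were lower and 3 higher (12 and 4 adjusted over the list alone), with the ATP sulfurylase MET3 at -2.76 ± 0.30 and the S-adenosylmethionine permease SAM3 at -1.33 ± 0.28. In contrast MMP1, a permease for S-methylmethionine, was higher by 1.79 ± 0.30. The adjusted p was 3.88e-07 for nitrogen catabolite repression and for ribosomal proteins, 0.00125 for lipids, 0.00141 for ergosterol and 0.0108 for sulfur. With an estimated correlation none passed, at adjusted p = 0.439, 0.698, 0.546, 0.698 and 0.698.

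Stationary phase and chaperone genes were more often higher than lower in ITD00185 at 96 h, though most did not pass. Of 36 genes of stationary phase and of the stress factors Msn2 and Msn4, 11 were higher and 0 lower (13 and 0 adjusted over the list alone), with GRE1 at 4.55 ± 0.52, SPG1 at 3.72 ± 0.33, MSC1 at 2.66 ± 0.47 and the small heat shock protein HSP12 at 2.20 ± 0.42. Of 30 heat shock proteins and chaperones 9 were higher and 1 lower (15 and 2 adjusted over the list alone), with a median of 1.12 and list medians of 1.13 to 1.79 on the ITD00185 arrays against 0.29 to 0.59 on the T73 arrays. In the defence against oxidative stress 10 of 35 were higher and 2 lower (11 and 2 adjusted over the list alone), with the mitochondrial superoxide dismutase SOD2 at 3.48 ± 0.39 and the peroxiredoxin AHP1 at 2.44 ± 0.30. The medians of that list on single arrays overlapped (-0.41 to -0.28 in ITD00185 against -0.68 to -0.31). Of 33 proteasome genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone), with RPN12 at 2.90 ± 0.58 and RPN6 at 1.54 ± 0.27. The adjusted p was 0.00125 for stationary phase, 0.00235 for chaperones, 0.0459 for oxidative stress and 0.00125 for the proteasome, and adjusted p = 0.439, 0.698, 0.546 and 0.698 with an estimated correlation. The proteasome list missed the threshold with scaled arrays (0.105), after quantile normalization (0.13) and with the shared profile removed (0.0956). That of oxidative stress was not the same in 11 of 21 alternatives, among them centred arrays (0.0593), a replicate block (0.0571) and 7 of 12 arrays left out in turn, with the highest adjusted p without T73 96 h replicate 2 (0.0921). The chaperone median went from 1.12 to 0.73 with scaled arrays, 0.67 after quantile normalization and 0.76 with the shared profile removed, with the call kept. In all, 12 of 40 lists were called at 96 h.

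Averaged over both times, the strains differed most in genes that differed at each time. ASP3-2 stood at -8.21, ASP3-4 at -8.08, ASP3-3 at -6.61 and ASP3-1 at -6.48, the meiotic chromosome protein RED1 at -5.73 and DAL5 at -5.24. In the other direction IRC9 and ZNF1 both stood at 6.61. HXT13 (2.17), MAL33 (3.12) and IMA1 (1.99) were higher in ITD00185, and so was the sulfite pump SSU1, with 2.49 ± 0.38 at 48 h and 2.25 ± 0.38 at 96 h. Its 96 h call was lost after quantile normalization (adjusted p 0.068). HXK1 was higher by 2.42 in the mean and by 2.04 ± 0.48 at 96 h, where it missed the threshold without T73 96 h replicate 3 (1.95, adjusted p 0.0523). Its 96 h call was not the same in 3 of 25 alternatives, with an adjusted p of at most 0.0579. For the mean 1322 genes passed, 476 higher and 846 lower in ITD00185, or 579 and 664 with centred arrays, 807 of them by 2-fold or more. The count was 2133 with weights for arrays. By time, 124 genes were higher at both (84.5 expected if the times were independent) and 185 lower at both (152.7 expected). Another 29 were higher at 48 h and lower at 96 h (73.8 expected) and 229 were lower at 48 h and higher at 96 h (174.8 expected). Across genes the differences at the 2 times correlated at r = -0.10, where genes are not independent replicates.

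**Figure D3:**
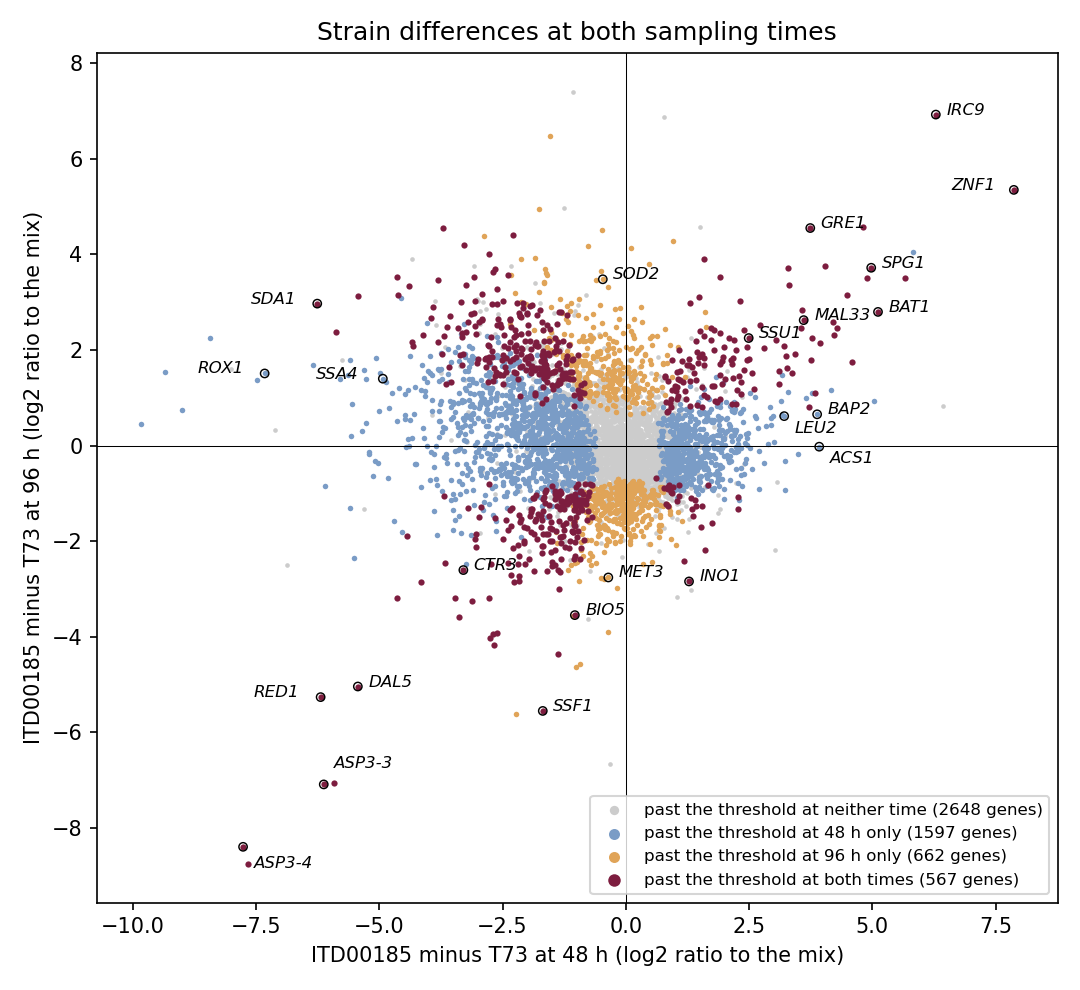
Difference between ITD00185 and T73 in log2 ratio to the mix at 48 h (horizontal axis) and at 96 h (vertical axis) for each gene tested, coloured by the times at which it passed the threshold, with named genes circled. The ASP3 copies, DAL5 and RED1 lay low at both times and IRC9 and ZNF1 high at both. ROX1, SDA1 and SSA4 lay low at 48 h only, and SSF1 lay lower at 96 h (-5.55) than at 48 h (-1.68).

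The difference between the strains changed from 48 h to 96 h in 2080 genes, by the test of the change itself. It moved upward in ITD00185 relative to T73 for 1333 and downward for 747, or for 1117 and 1122 with centred arrays. Across genes the change correlated at r = 0.63 with the mean profile of all groups. Among genes with a symbol, the largest upward changes that held with each array left out were those of TFA1, a subunit of the general factor TFIIE (10.29 ± 1.36, with 1 array value beyond 10), SDA1 (9.23 ± 1.17), BRF1 of TFIIIB (8.85 ± 1.16) and ROX1 (8.84 ± 0.97). BUB1 (10.69 ± 3.24) and LCP5 (9.75 ± 2.76) also rested on a value beyond 10, and without T73 48 h replicate 2 they stood at 6.96 and 5.35. With scaled arrays TFA1 stood at 6.54, below SDA1 at 6.96, and with the shared profile removed ROX1 stood at 5.52. The largest downward changes, again among genes with a symbol, were those of the aquaporin AQY1 (-4.15 ± 0.69), INO1 (-4.12 ± 0.60), the acetyl-CoA synthetase ACS1 (-3.94 ± 0.62), SSF1 (-3.87 ± 0.55) and MET17, the homocysteine synthase (-3.78 ± 0.77). AQY1 missed the threshold with scaled arrays (-1.45) and with the shared profile removed (-1.10). With the shared profile removed the change was -2.28 for ACS1 and 3.46 for SSA4, and with scaled arrays it was -2.10 for BAP2 and -1.55 for SAM3, with each call kept. ACS1 went from 3.92 ± 0.44 at 48 h to -0.02 ± 0.44 at 96 h, and the gluconeogenic FBP1 from 2.44 ± 0.31 to -0.28 ± 0.31. Among chaperones 20 of 30 genes changed upward and 1 downward (21 and 2 adjusted over the list alone), among them SSA4 by 6.33 ± 0.91, and the median of 2.97 became 2.31 with scaled arrays, 2.00 after quantile normalization and 1.73 with the shared profile removed. In branched-chain amino acid synthesis 0 of 11 changed upward and 7 downward (0 and 8 adjusted over the list alone), among them LEU4 by -2.92 ± 0.56, and BAP2 changed by -3.22 ± 0.38. In sulfur assimilation 3 of 34 changed upward and 13 downward (3 and 14 adjusted over the list alone), with MET3 at -2.40 ± 0.43 and SAM3 at -2.67 ± 0.39. The proteasome, with 21 of 33 changed upward and 0 downward (21 and 1 adjusted over the list alone), had a median of 1.68 that fell below the threshold with scaled arrays (0.39, adjusted p 0.176). The adjusted p of these 4 lists was 0.000152, 0.000853, 0.000853 and 7.38e-05, and adjusted p = 0.609 for each with an estimated correlation. The count of genes was 1215 with scaled arrays, 1248 after quantile normalization, 1264 without T73 96 h replicate 3 and 3275 with weights for arrays.

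**Figure D4:**
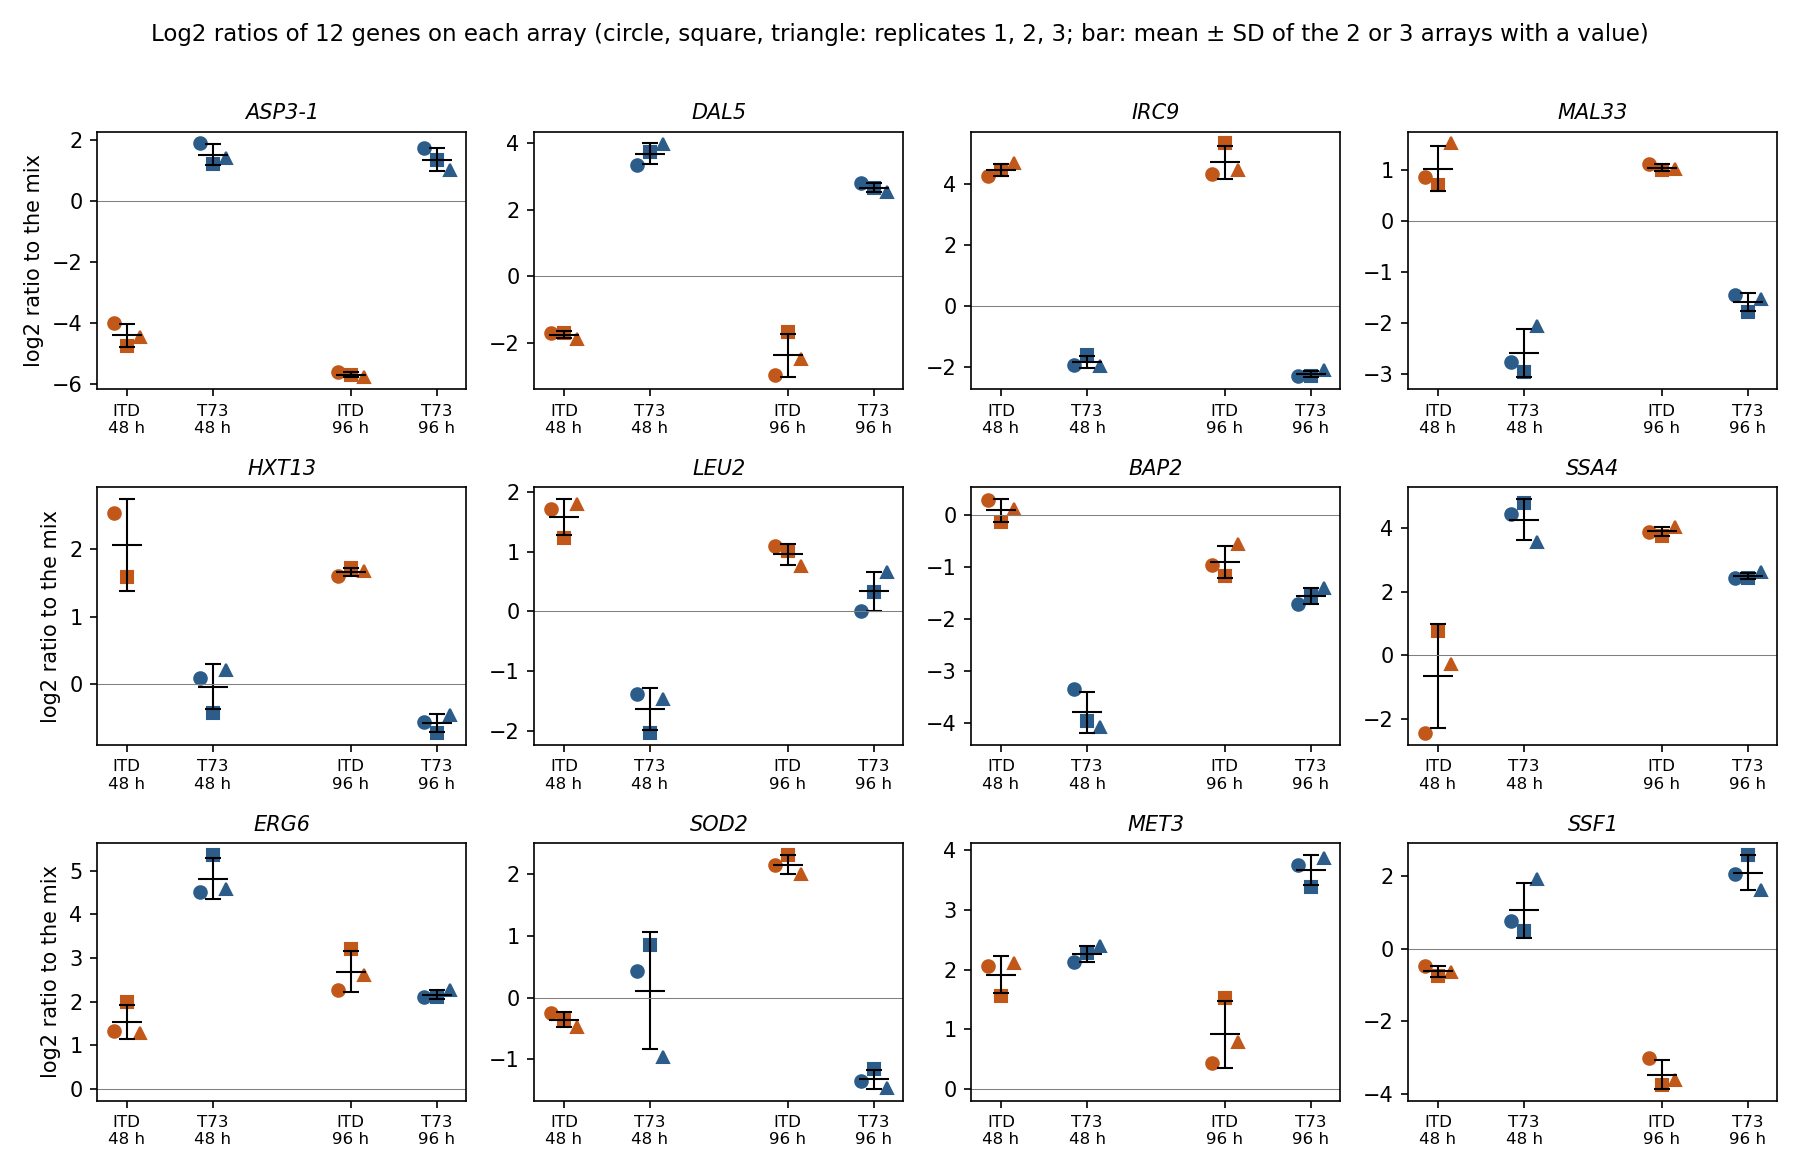
Log2 ratio to the mix of 12 genes on each array, with circles, squares and triangles for replicates 1, 2 and 3, and bars for the mean and standard deviation of the 2 or 3 arrays with a value. ASP3-1 and DAL5 were separated by strain at both times, LEU2 and BAP2 at 48 h (3.21 and 3.88), and SOD2 and MET3 at 96 h (3.48 and -2.76).

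Ratios to the mix changed between the times in 357 genes of ITD00185 (209 up, 148 down) and in 1772 genes of T73 (461 up, 1311 down, or 775 and 927 with centred arrays). By the labels the mix was of the time of each array, so these are changes against a mix that may also have changed. The mean over both strains was planned as a check of the mix. The mean was to stay near 0 at each time if the mix were an even pool of both strains of that time. Its change was to hold the shared time course if the same mix served all arrays. The mean over both strains passed in 317 genes (47 up, 270 down), and with centred arrays in 140 (45 up, 95 down), 137 of them among the 317. The count was 118 with scaled arrays, 136 after quantile normalization, 63 without T73 96 h replicate 1 and 750 without ITD00185 48 h replicate 2. This count depended so much on single arrays that the part on a time course stayed open. The mean profile of the 4 groups did not stay near 0, with a standard deviation of 1.17 over genes. Medians of cytosolic ribosomal proteins in ITD00185 and T73 were 0.98 and 1.61 at 48 h, and 0.70 and 1.43 at 96 h. Those of other lists, such as glycolysis, lay on both sides of 0. This argues against an even pool for genes such as the ribosomal ones, unless a dye bias raised their ratios. Such a bias cannot be separated here. In T73 the ratio of SDA1 fell by 6.98 ± 0.82 and that of MRP51 by 3.68 ± 0.51, whereas those of SUC2 (2.97 ± 0.48), BAP2 (2.24 ± 0.27) and LEU2 (1.97 ± 0.28) rose. In ITD00185 the ratios of ROX1 (5.01 ± 0.69), SSA4 (4.55 ± 0.64) and HSP42 (3.26 ± 0.45) rose, and that of SSF1 fell by 2.83 ± 0.39. These 9 calls held with each single array left out and with the arrays centred, scaled or quantile-normalized. Printed genes were mainly chosen because their calls held with each array left out, so this is no measure of the other calls. The count in ITD00185 depended on single arrays, with 21 genes without ITD00185 48 h replicate 1 and 2104 without ITD00185 48 h replicate 2, and it was 44 in a fit of its own 6 arrays. In T73 it was 925 without T73 96 h replicate 1, 759 with scaled arrays and 766 after quantile normalization.

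Of the genes fixed by name for their part in fermentation, all but SSU1 passed at 48 h only or at neither time. The invertase SUC2 did not pass at 48 h (0.58 ± 0.48, adjusted p 0.35) or 96 h (-0.73 ± 0.48, adjusted p 0.28), although it passed at 48 h with the shared profile removed (2.63) and at 96 h after quantile normalization (-1.65, adjusted p 0.0475) and with weights for arrays (0.049). The general amino acid permease GAP1 was lower in ITD00185 at 48 h (-1.46 ± 0.31) and did not pass at 96 h (-0.85 ± 0.31). Its adjusted p at 48 h was 0.0515 in a fit of only the arrays of that time, and at 96 h it passed in that fit (0.0178), with weights for arrays (0.00096), without T73 48 h replicate 3 (0.0342) and with the shared profile removed (0.0461). The glyceraldehyde phosphate dehydrogenase TDH3 was higher at 48 h (1.58 ± 0.34) and not at 96 h (0.15 ± 0.34). The flocculin FLO11 (1.85 ± 0.59), the hexose transporter HXT1 (1.07 ± 0.31), the alcohol dehydrogenase ADH1 (1.41 ± 0.48) and the alcohol acetyltransferase ATF1 (0.85 ± 0.29) passed at 48 h, but each lost its call without at least 1 array. In this order the 48 h call was not the same in 11, 7, 11 and 12 of 25 alternatives. Without ITD00185 48 h replicate 1 the values were 0.88 for HXT1, 0.87 for ADH1 and 0.71 for ATF1. Without T73 48 h replicate 2 that of FLO11 was 1.82 with an adjusted p of 0.0721. With scaled arrays all 4 calls were lost (adjusted p 0.219, 0.219, 0.0522 and 0.124). None of these 4 passed at 96 h (-0.54 ± 0.59, 0.15 ± 0.31, -0.85 ± 0.48 and -0.64 ± 0.29), though with weights for arrays ADH1 (adjusted p 0.0208) and ATF1 (0.0154) did. The pyruvate decarboxylase PDC1 (0.45 ± 0.50 at 48 h, -1.12 ± 0.50 at 96 h), the glycerol phosphate dehydrogenase GPD1 (0.65 ± 0.32, -0.61 ± 0.32) and actin ACT1 (0.61 ± 0.46, -0.28 ± 0.46) passed at neither time. Without ITD00185 48 h replicate 2, however, ACT1 (1.24, adjusted p 0.0046) and GPD1 (0.90, adjusted p 0.0331) passed at 48 h, and PDC1 passed at 96 h (-1.12, adjusted p 0.0471). PDC1 passed at 96 h also in a fit of only the arrays of that time (0.0157) and with weights for arrays (0.00236). With those weights GPD1 passed at 96 h (0.0206) and ACT1 at 48 h (0.0227). GPD1 also passed at 48 h after quantile normalization (1.38, adjusted p 0.0499) and with the shared profile removed (1.15, adjusted p 0.03).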

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

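The comparison of the change between times and the tests on regrouped arrays were written before the data were examined. The 3 patterns weighed here were chosen after the values were seen, with the prediction of each test written before it was run. A change made to 1 rule after a value was seen is named with the pattern.

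The results in this part are listed because the difference between the strains was not the same at 48 h and at 96 h by the test of the change. This held for 2080 genes. Among 16 gene lists called for the change, the median moved upward for chaperones (2.97), mitochondrial ribosomal proteins (1.89), the proteasome (1.68) and ribosome biogenesis (1.53). It moved downward for branched-chain amino acid synthesis (-1.64), glycolysis (-1.32) and gluconeogenesis and the glyoxylate cycle (-1.10). The same held for amino acid permeases (-1.07), pyruvate to ethanol and acetate (-1.06), the citric acid cycle (-1.05), sucrose, fructan and maltose use (-1.02) and cell wall mannoproteins (-1.0). Smaller downward moves were those of subtelomeric helicases and COS genes (-0.99), sulfur assimilation (-0.96), iron uptake (-0.94) and ester and higher alcohol formation (-0.83). All 16 were lost with an estimated correlation, at adjusted p = 0.609 to 0.632. The ribosome biogenesis list was not the same in 12 of 21 alternatives, among them 6 of 12 arrays left out in turn, with the highest adjusted p without T73 96 h replicate 3 (1.39, adjusted p 0.0759). That of subtelomeric genes was lost without ITD00185 48 h replicate 2 (-1.02, adjusted p 0.0537) and without T73 48 h replicate 3 (-0.73, adjusted p 0.0533). With scaled arrays, after quantile normalization and with the shared profile removed, in this order, 5 of these lists missed the threshold each time. The changes and adjusted p were 0.57 (0.531), 0.50 (0.482) and 0.38 (0.765) for ribosome biogenesis, and 0.39 (0.176), 0.23 (0.162) and 0.06 (0.321) for the proteasome. They were -0.34 (0.299), -0.63 (0.16) and -0.38 (0.317) for gluconeogenesis, and -0.63 (0.0676), -0.84 (0.0542) and -0.76 (0.124) for pyruvate to ethanol and acetate. For subtelomeric genes they were -0.50 (0.338), -0.66 (0.16) and -0.61 (0.292). Mitochondrial ribosomal proteins stayed called with scaled arrays (0.58) and after quantile normalization (0.53), but not with the profile removed (0.24, adjusted p 0.129). Iron uptake was lost with scaled arrays (-0.71, adjusted p 0.0503) and with the profile removed (-0.63, adjusted p 0.0707). Other lists were called for the change only under these alternatives, so that 17, 16 and 15 were called in the same order, 10, 11 and 9 of them among the 16. Cytosolic ribosomal proteins, not called as deposited (median -0.003, adjusted p 0.358), were called downward in all 3, at -1.39 (7.12e-11), -1.53 and -1.54. Aromatic amino acid and histidine synthesis (-1.05, -1.21 and -1.12), NAD metabolism (-1.45, -1.58 and -1.42), cell cycle and DNA replication (-0.69, -0.75 and -0.86) and seripauperins (1.57, 1.09 and 1.47) were called in all 3. With an estimated correlation on the values as deposited these 5 lists were at adjusted p = 0.92, 0.632, 0.632, 0.841 and 0.919.

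Among named genes the difference moved upward in ITD00185 relative to T73 for TFA1 (10.29), SDA1 (9.23), BRF1 (8.85), ROX1 (8.84), MIG1 (8.27) and RCF1 (7.39). Next came ENV11 (7.28), YAP1801 (7.19), PIL1 (6.69), MIL1 (6.42), SSA4 (6.33) and STI1 (5.99). They were followed by SSE1 (5.56), MRP51 (5.56), ENT3 (5.00), HSP42 (4.45), RPN12 (4.41) and SOD2 (3.95). The smallest were ERG6 (3.82), MSC1 (3.47), HSP12 (3.15), RSM10 (2.98), ERG20 (2.63), RPN6 (2.63) and AHP1 (1.64). It moved downward for AQY1 (-4.15), INO1 (-4.12), ACS1 (-3.94), SSF1 (-3.87), MET17 (-3.78), BAP2 (-3.22), LEU4 (-2.92) and FIT3 (-2.84). Next came FBP1 (-2.73), SAM3 (-2.67), ZPS1 (-2.67), LEU2 (-2.59), BIO5 (-2.51), SDH2 (-2.46) and MET3 (-2.40). The smallest were LEU9 (-2.39), BAT1 (-2.32), FUM1 (-2.32), CHO1 (-2.24), ACO1 (-1.97), AAD3 (-1.52) and ATF1 (-1.50). These calls held with each single array left out. With scaled arrays the threshold was missed by ERG20 (0.78), AHP1 (0.89), AQY1 (-1.45), FIT3 (-2.44), ZPS1 (-1.85), BIO5 (-0.10), SDH2 (-1.11), ACO1 (-1.65), AAD3 (-1.12) and ATF1 (-1.03). After quantile normalization it was missed by ERG6 (1.14), HSP12 (2.03), ERG20 (0.79), AHP1 (0.69), FIT3 (-3.00), ZPS1 (-2.24), ACO1 (-1.79), AAD3 (-1.50) and ATF1 (-1.11). With the shared profile removed it was missed by HSP42 (1.96), ERG6 (0.99), ERG20 (0.80), AHP1 (0.52), AQY1 (-1.10), ZPS1 (-1.83) and BIO5 (0.22). Changes that kept their call could also shrink. The lowest values over all alternatives were 1.03 for RPN6, 1.53 for RSM10, 2.12 for RPN12, 2.79 for ENT3, 2.88 for SSE1 and 2.95 for MRP51.

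For 12 further named genes the change was called with all arrays but lost without at least 1 array, and 1 such array is given for each. Over 24 alternatives the call was not the same in 16 for ASP3-3, 15 for DAL1, 14 for FLO11, 13 for ECM8 and 12 each for ASP3-1 and TDH3. It was not the same in 11 for GPD1, 8 for BUB1, 5 for ADH1 and 3 for RPL23B. For LCP5 this was so in 8 of 22 and for ZNF1 in 3 of 23. Without ITD00185 48 h replicate 1 the values and adjusted p were 10.28 and 0.0595 for BUB1 (10.69 with all arrays) and -1.94 and 0.0775 for ZNF1 (-2.52). Without ITD00185 48 h replicate 3 they were -0.85 and 0.0928 for ASP3-3 (-0.96). Without ITD00185 96 h replicate 2 they were 1.18 and 0.0997 for DAL1 (1.30), 9.90 and 0.0629 for LCP5 (9.75), -1.89 and 0.0625 for ADH1 (-2.27) and -1.06 and 0.11 for GPD1 (-1.26). Without ITD00185 96 h replicate 3 they were -1.11 and 0.115 for ECM8 (-1.37) and -2.15 and 0.0979 for FLO11 (-2.38). Without T73 96 h replicate 1 they were -0.95 and 0.115 for ASP3-1 (-1.14), and without T73 96 h replicate 3 they were -1.37 and 0.0523 for RPL23B (-1.46) and -1.29 and 0.0899 for TDH3 (-1.43).

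ITD00185 48 h replicate 2 resembled the ITD00185 arrays of 96 h more than its own group, which could come from a mislabelled time point, from a larger amplitude of the profile shared by all arrays, or from a fermentation that had run ahead. On an axis from the other 48 h arrays at 0 to the 96 h arrays at 1 it lay at 0.762, with a range of 0.694 to 0.786 over baselines and left-out arrays. Single 96 h arrays placed against the other 96 h arrays lay from 0.80 to 1.04. The bound of 0.8 written beforehand against mislabelling was met, but by less than the spread of the position, and after the value was seen this was read as leaving mislabelling open. Amplitude alone did not account for the likeness, since with the T73 profile removed its mean r to its own group was still lower than to the 96 h arrays by -0.369 (r of 0.27 to 0.32 against 0.63 to 0.71 across genes). No sampling record or density is in the labels, so a fermentation that had run ahead was not tested.

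The differences between strains ran along a profile that all arrays shared, at r = -0.48 across genes with the profile of the 96 h arrays for 48 h and 0.33 with that of the 48 h arrays for 96 h. With the profile of the 96 h arrays removed, 58.8% of the genes called at 48 h stayed called in the same direction, between the bounds of 50% and 67% set beforehand, so how much of the 48 h difference is amplitude is open. With the profile of the 48 h arrays removed, 84.5% of those called at 96 h stayed, above the bound, and amplitude of this profile does not account for most of them. The change between times correlated at r = 0.63 across genes with the mean profile of all groups, which holds the arrays compared. No bound was set for the change, so how much of it is amplitude is open. The arrays carried the profile with slopes from 0.44 to 1.45, which could reflect the makeup of the mix, labelling, or the physiology of the cultures. With the profile removed the 48 h lists of cytosolic and mitochondrial ribosomal proteins, the proteasome, ribosome biogenesis, seripauperins, gluconeogenesis, stationary phase, iron uptake and amino acid permeases lost their calls, and the chaperone median shrank from -1.94 to -0.59 with its call kept.

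Differences shared by both times fell in neighbouring genes more often than in 10000 shuffles, with 26 pairs against a mean of 8.75 and a highest count of 24 (permutation p 1e-04, the smallest that many shuffles can give). Neighbours were measured genes that follow each other by systematic name, so an unmeasured one may lie between them. Examples are EDS1 (YBR033W), PDX3 (YBR035C) and CSG2 on one chromosome arm and BOR1, YNL276C, MET2 and CAF120 on another, all higher in ITD00185 at both times. These examples come from the set that kept overlapping reading frames, and overlap within them was not tested. Overlapping reading frames did not account for it, with 19 pairs against a mean of 7.93 without them (permutation p 6e-04). Gene presence or copy number could give such pairs, and so could co-regulated neighbours. Without DNA data the choice stays open.

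Regrouping the arrays tested whether counts as large arise by chance. For comparisons with 10 splits these are too few for a share under 0.05. The real grouping gave the highest count in 1 of 10 splits for genes at 48 h (2164 against 310 at most), genes at 96 h (1229 against 0), the ratio changes in ITD00185 (357 against 1) and in T73 (1772 against 0), and for lists at 48 h (22 against 17) and at 96 h (12 against 11). Where 100 splits were used, these were the real grouping and a random draw of the others. The splits for the change between times and for the mean of both times exchanged strain labels within each time. The real count was reached in a share under 0.05, which argues against no strain difference at either time. It cannot exclude chance for the change or the mean as such. In the change 1 split reached 2080 and the next gave 1690. In the mean 2 splits reached 1322, and the other, at 2080, turns the strain labels at 96 h and so equals the change. The splits for the mean ratio change exchanged times within each strain and bear only on no time difference in either strain. There 3 splits reached 317, with 2036 the highest, also a share under 0.05. For the lists called for a change chance is not excluded, since 13 of 100 splits gave as many as 16 and up to 21.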

How the results depend on the processing

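Removing the shared profile, running lists on scaled and quantile-normalized arrays, and the estimated correlation without ITD00185 48 h replicate 2 were chosen after the data were seen. Of the values for named genes under the alternatives, 11 reversed, as did 12 for lists, and the cause was not tested unless the alternative itself shows it. With the arrays scaled to one spread the counts moved to 1252 (48 h), 1215 (change), 227 (ITD00185), 759 (T73), 118 (mean ratio change) and 14 lists at 48 h, and after quantile normalization to 1265, 1248, 203, 766, 136 and 14. With the shared profile removed 14 lists were called at 48 h. Centred arrays gave 140 for the mean ratio change. For seripauperins in the change, with a median of 0.06 as deposited, reversed means that the direction of the test turned. Scaled arrays reversed seripauperins at 48 h (-0.25) and in the change (1.57), and cytosolic ribosomal proteins at 48 h (0.16). They also reversed biotin in the change (0.96), ASP3-3 in the change (0.21), and RPL23B (0.11) and RPL10 (0.0365) at 48 h. Quantile normalization reversed seripauperins at 48 h (-0.11) and in the change (1.09), cytosolic ribosomal proteins (0.24), RPL23B (0.22) and RPL10 (0.15) at 48 h. Removing the shared profile reversed seripauperins (-0.49), cytosolic ribosomal proteins (0.41), the proteasome (0.15), RPL23B (0.53), RPN6 (0.0491) and MET3 (1.40) at 48 h. In the change it reversed biotin (1.08), seripauperins (1.47), ASP3-1 (0.16), ASP3-3 (0.56) and BIO5 (0.22). A fit of only the arrays compared has fewer residual degrees of freedom and its own estimate of the spread. Its counts were 794 at 48 h, 2466 at 96 h and 44 in ITD00185. The main fit shared the variance of each gene over both times. The median standard deviations in ITD00185 and T73 were 0.50 and 0.44 at 48 h against 0.27 and 0.24 at 96 h. That more genes differed at 48 h than at 96 h thus held in the main fit, but not in fits of each time alone. Weights for arrays gave 3178 at 96 h, 2133 for the mean, 3275 for the change, 2835 in ITD00185 and 1114 for the mean ratio change. A 2-fold minimum left 807 for the mean and 192 for the mean ratio change. A threshold of 0.01 left 1028, 462, 700, 679, 22, 613 and 10, in the order 48 h, 96 h, mean, change, ITD00185, T73 and mean ratio change. With an estimated correlation 0 lists were called at 48 h, 0 at 96 h and 0 for the change, and 0 in each also without ITD00185 48 h replicate 2. With single arrays left out, where the remaining arrays of a group are assumed to vary like the others, counts ran from 1414 to 2832 at 48 h, 537 to 1799 at 96 h, 971 to 1770 for the mean, 1264 to 2903 for the change and 21 to 2104 in ITD00185. They ran from 925 to 2273 in T73 and 63 to 750 for the mean ratio change, and lists from 20 to 23, 9 to 15 and 15 to 17. The labels give replicate numbers, but these do not pair samples, and deviations of samples with the same number correlated weakly or not at all (r across genes of -0.04, 0.19 and 0.27 at 48 h and 0.03, -0.07 and -0.14 at 96 h). A replicate block gave 2370, 1439, 1449, 2249, 683, 1914 and 432 genes and 22, 11 and 15 lists, a change of over 1.5 times in ITD00185 alone. The other alternatives (no filter on missing values, only genes with a value on all arrays, each probe on its own, a robust prior, extreme values set to missing) left all counts of genes within 1.5 times. Signal over background was not analysed here, so its part in the precision is unknown.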

Other observations

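The groups in this part were picked from the fixed lists after their values were seen. In copper and zinc uptake 3 of 17 genes were higher and 4 lower in ITD00185 at 48 h (3 and 4 adjusted over the list alone), and 2 and 5 at 96 h (2 and 5). The copper transporter CTR3 was lower at both times (-3.30 ± 0.26 and -2.60 ± 0.26), and so was FRE7, a reductase induced by copper starvation (-1.93 ± 0.22 and -1.32 ± 0.22), whereas the zinc-responsive ZPS1 was higher at 48 h (3.77 ± 0.51) and did not pass at 96 h (1.10 ± 0.51). In biotin uptake and synthesis 3 of 6 genes were lower and 0 higher at 48 h and again at 96 h (3 and 0 adjusted over the list alone at each time), at 96 h with the biotin intermediate permease BIO5 at -3.55 ± 0.36 and the aminotransferase BIO3 at -2.25 ± 0.35. That list was called at 96 h (adjusted p 0.00727, and adjusted p = 0.698 with an estimated correlation), but not with scaled arrays (0.231), after quantile normalization (0.0734) or with the shared profile removed (0.242). At 48 h it was not called as deposited (-1.02, adjusted p 0.173), but in the same order at -2.45 (0.000154), -1.67 (0.00167) and -2.73 (0.000118), with adjusted p = 0.55 with an estimated correlation on the values as deposited. In ester and higher alcohol formation 6 of 20 genes were higher and 4 lower at 48 h (7 and 4 adjusted over the list alone), and 2 and 6 at 96 h (2 and 7). The ethyl ester synthases EEB1 (-2.38 ± 0.27 at 48 h, -1.77 ± 0.27 at 96 h) and EHT1 (-1.90 ± 0.33 at 96 h) were lower in ITD00185. EHT1 also passed at 48 h, but lost its call with each of 4 arrays left out in turn (at most adjusted p 0.0778, at -0.99, without ITD00185 48 h replicate 1) and with scaled arrays (-0.81, adjusted p 0.101).

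Subtelomeric helicase and COS genes were higher in ITD00185 for 7 of 18 genes at 48 h and lower for 1 (7 and 1 adjusted over the list alone, list adjusted p 0.00202, and adjusted p = 0.365 with an estimated correlation), with COS4 at 1.91 ± 0.35. At 96 h 2 were higher and 2 lower (2 and 2 adjusted over the list alone), with a median of 0.08 and COS4 at 1.70 ± 0.35. The list was not called then (list adjusted p 0.649, and adjusted p = 0.698 with an estimated correlation). The aryl-alcohol dehydrogenase AAD3 was higher by 3.77 ± 0.23 at 48 h and 2.25 ± 0.23 at 96 h. Both belong to families with near-identical copies. Among 41 genes of meiosis and sporulation, a list kept for another cell type, 6 were higher and 6 lower at 48 h (6 and 5 adjusted over the list alone) and 2 and 6 at 96 h (2 and 5), with RED1 lower at both times (-6.19 ± 0.62 and -5.26 ± 0.62). Of 24 haploid and mating-type genes 4 were higher and 4 lower at 48 h (4 and 4 adjusted over the list alone), and 0 and 1 at 96 h (0 and 1). MET2, the homoserine acetyltransferase, was higher at both times (1.59 ± 0.35 and 1.69 ± 0.35), against the direction of most called sulfur genes at 96 h.

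Other lists called at 48 h were gluconeogenesis and the glyoxylate cycle (6 higher and 3 lower of 19, 6 and 3 adjusted over the list alone), amino acid permeases (7 and 2 of 18, 7 and 2 adjusted over the list alone) and NAD metabolism (4 and 0 of 12, 4 and 0 adjusted over the list alone). So were oxidative stress (12 and 6 of 35, 15 and 7 adjusted over the list alone), stationary phase (13 and 5 of 36, 13 and 9 adjusted over the list alone), iron uptake (7 and 2 of 25, 8 and 2 adjusted over the list alone) and seripauperins (4 and 0 of 20, 4 and 0 adjusted over the list alone). In this order adjusted p = 0.428, 0.532, 0.532, 0.365, 0.446, 0.446 and 0.573 with an estimated correlation. The medians of seripauperins (0.27 to -0.25) and of gluconeogenesis (0.52 to -0.0175) turned with scaled arrays. The seripauperins are a family with close copies, which a probe may not separate. The lists of gluconeogenesis (0.321), oxidative stress (0.0749), stationary phase (0.274) and iron uptake (0.24) missed the threshold with scaled arrays. NAD metabolism was also lost without ITD00185 48 h replicate 3 (0.0646), T73 48 h replicate 1 (0.0551) or T73 48 h replicate 2 (0.0533), and stationary phase without T73 48 h replicate 3 (0.0597). At 96 h aromatic amino acid and histidine synthesis (0 higher and 4 lower of 18, 0 and 5 adjusted over the list alone) and mitochondrial ribosomal proteins (7 and 1 of 53, 4 and 1 adjusted over the list alone) were called as well, at adjusted p = 0.698 each with an estimated correlation. The first was lost without ITD00185 96 h replicate 1 (0.0927), ITD00185 96 h replicate 3 (0.0643) or T73 96 h replicate 3. The second was lost without ITD00185 96 h replicate 3 (0.0643) or T73 96 h replicate 3 (0.0606), with scaled arrays (0.328), after quantile normalization (0.371) and with the shared profile removed (0.347).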
